A study of Mus musculus with 18 samples.

How the data were processed

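Messenger RNA of sorted mouse CD8+ T cells was measured with droplet-based 5' single-cell sequencing in 6 libraries, each with a matching library of hashtag oligonucleotides that mark the sorted population a cell came from. T cell receptor libraries of the same 6 loadings were not analysed here. The authors deposited, per the file headers, whole-number UMI counts per gene and barcode and whole-number counts per hashtag and barcode, neither of them normalized, from Cell Ranger on the mouse build GRCm38 (mm10). Per the submitters' processing notes, reads were demultiplexed with bcl2fastq and later steps used Seurat 4, but no deposited object of that later step was used here. How reads shared by near-identical genes were counted is not given in the sources used here, so values of Klra, Ifit, Tgtp and Lilr family members and of Gzmd, Gzme and Gzmf are uncertain. Gene positions come from GENCODE vM21 (GRCm38), in which all 327 named genes were found. The matrices hold no feature for the tdTomato or Cre sequences.

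The deposited hashtag sheet names, for each library and tag, a tissue, a sorting gate and in most cases a day. The cells of 1 tag in 1 library formed 1 sample. The sheet names no animals, so the number of mice behind a sample is unknown. "DN" in the sheet was read as LAG3-tdT-. Libraries 3 and 4 together hold 1 full set of gates and share the day 19 LAG3+tdT+ tag, so they were treated as 1 pool (pool 3/4). Library 3 holds the day 11 tumour gates and the day 19 LAG3-tdT+ gate, library 4 holds the day 19 LAG3-tdT- gate and the lymph nodes, so comparisons within pool 3/4 set samples of 2 libraries side by side. Labels of 3 samples of library 1 give day 72, 73 and 74 in turn, and the sheet's day 72 was used. Lymph nodes that the sheet gives without a day (9 samples of libraries 5 and 6) entered no comparison. For library 5 the sheet gives node 1 for the day 11 CD44+tdT- sample and node 2 for the CD44+tdT+ sample.

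Barcodes present in both matrices were kept with at least 1000 UMIs, at least 500 genes and at most 10% mitochondrial UMIs. They also needed at least 1 UMI of Cd8a or Cd8b1 and at most 1 UMI of the melanoma, myeloid, B cell and erythroid markers. Cd74, Ctss, H2-Aa, Apoe and Igkc did not count toward this last limit. The last limit removed between 28.78% and 47.22% of barcodes per library, mostly through Ighm. A cell was assigned to a tag with at least 10 UMIs and at least 3 times the UMIs of the next tag of its library. Samples with fewer than 20 cells were left out, which removed the 16 cells of the day 11 LAG3+tdT+ sample of pool 3/4. Scrublet (scanpy 1.11.5) called 0 doublets in each of the 6 libraries and so had not worked on these data. Doublets were therefore treated through the hashtag ratio, and leaving out the barcodes with the highest scores was an added alternative.

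UMI counts were summed per sample and tested with edgeR 4.0.16 (R 4.3.3): filterByExpr, TMM scaling, glmQLFit and glmQLFTest with 1 mean per group and all replicated groups in 1 fit. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 among 11151 genes, separately for each comparison. Every adjusted p of a gene in the text is from edgeR's quasi-likelihood test, fold changes are on the log2 scale with their standard error (SE), and levels are edgeR's CPM values after TMM scaling as mean ± SD over samples. The p-values measure only the spread between these samples, since the number of mice is unknown. A fold against a group at 0 UMIs is given as a lower bound against 3 counts over the group. Gene lists were tested with limma 3.58.1 (camera on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the 27 lists with enough measured members). Each list was also tested with a correlation estimated from the data and with fry, which tests only whether a list's own genes move one way.

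The genes named were set by a rule made before the data were examined. It takes up to 10 genes per direction with the largest fold change that passed, whose samples did not overlap and whose mean reached 20 CPM. It adds fixed genes in every comparison, among them Lag3, Tcf7, Tox, Pdcd1, Slamf6, Havcr2, Il7r, Id3 and Gzmb, and up to 4 members per list. Genes named outside it are said to be chosen after their values were seen. The 30 lists, also fixed before the data were examined, cover stem-like progenitor, terminal exhaustion, central memory and naive, effector, cycling, interferon, cytotoxic, cytokine and chemokine, inhibitory receptor, costimulatory receptor, tissue residency, homing and egress, killer lectin, T cell receptor and CD8, exhaustion factor, stemness factor, immediate early, hypoxia, glycolysis, oxidative phosphorylation, cholesterol, ribosomal and mitochondrial genes, and markers of CD4 T cells, NK and gamma-delta T cells, B cells, myeloid, stromal, melanoma and erythroid cells. Of the last kinds, the melanoma and erythroid lists had 0 measured members and the stromal list 2, so these 3 were not tested. Trgc1, Ero1a, Mx1 and Znf683 are not in the matrices under these symbols. Lag3, tdTomato and CD44 were used for sorting, and Lag3 is no finding between gates. Lag3 was nonetheless kept in the terminal exhaustion and inhibitory receptor lists, and Cd44 in the homing list. Member counts and p-values of these lists thus include a gene used for sorting.

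The library number marks a shared library, which pairs the samples of a pool. Over the pairs of a comparison, the correlation of deviations from the group means lay between 0.041 and 0.263 for day 19 LAG3-tdT+ against LAG3+tdT+, 0.107 and 0.324 for LAG3+tdT+ against LAG3-tdT-, 0.138 and 0.297 for LAG3-tdT+ against LAG3-tdT-, and 0.191 and 0.423 for the lymph node gates, and at day 11 between 0.296 and 0.538 for the lymph node gates. A fit with the pool as a block was run for every comparison.

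Shares of cells with a UMI were compared after thinning each cell to 1500 UMIs. This left out 39 of the day 19 tumour LAG3+tdT+ cells, 633 of LAG3-tdT+, 48 of LAG3-tdT-, 130 of the day 19 lymph node CD44+tdT+ cells and 82 of CD44+tdT-. The test was a two-sided exact permutation test of the samples' shares (scipy 1.17.1), adjusted over 80 tests. Free RNA was gauged in B cell-like barcodes, defined by at least 3 B cell marker UMIs. Groups with 1 sample were compared with exact 95% Poisson intervals of the UMI sums, which cover counting error only, and lists by their percentile among 10000 random lists of like expression. For these, folds add 0.5 UMIs and genes needed 50 CPM in 1 sample.

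The tests were tested on simulated data with 100 genes changed at each size, drawn from the means and depths of these samples. At a log2 change of 2, 82% were recovered for day 19 LAG3+tdT+ against LAG3-tdT-, 77% for LAG3-tdT+ against either other gate at day 19, 65% for LAG3+tdT+ against LAG3-tdT- at day 11, and 81% and 84% for the lymph node gates at day 19 and 11. In the same order, false calls were 5 of 136 calls, 4 of 112 and 3 of 111 for the 2 comparisons of LAG3-tdT+, 4 of 83, 3 of 120 and 13 of 142. For lymph node against tumour traced cells they were 6 of 121 at day 19 and 8 of 126 at day 11, and the shares exceeded 5% for the lymph node gates and for lymph node against tumour at day 11 alone. At a log2 change of 1 the recovered shares were 49%, 31%, 14%, 36% and 45% in the order given first. For day 19 LAG3+tdT+ against LAG3-tdT-, a raised list was found and 0 of 20 unchanged lists were called. The simulated genes varied independently of each other and without pool effects. The simulation therefore cannot tell how often unchanged lists or genes are called where genes move together.

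Alternatives for the fit, set before the data were examined, were edgeR's RLE (relative log expression) scaling, no low-count filter, DESeq2 1.42.0's test, limma-voom and the pool as a block. Alternatives for the cells, also set then, were a tag ratio of 10, Seurat 5.3.0 HTODemux at a quantile of 0.99, no CD8 or contaminant filter and at most 5% mitochondrial UMIs. Set then too were at least 50 cells, only the groups compared, leaving out cells with 2 or more cycling UMIs, and leaving out each sample in turn. Alternatives added after seeing the data were Ighm left out of the contaminant limit, a tag ratio of 10 in library 3 alone, library 3 left out, the highest Scrublet scores left out, and cells with a UMI of Cd4, Foxp3 or Zbtb7b left out. The planned comparison of cluster sizes was not run, because the genes that define clusters differ between the gates compared.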

Results

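CD8+ T cells were sorted from B16-F10 melanomas and lymph nodes of mice in which tamoxifen permanently switches on the red protein tdTomato in cells that express Lag3, an inhibitory receptor of activated and exhausted T cells. A tdT+ cell, or a cell it descends from, therefore had Lag3 activity when tamoxifen was given. This holds whatever the tdT+ cell carries on its surface at harvest. The sample records place all tamoxifen before the day 11 harvest. The time since labelling is thus longer at day 19 and longest at day 72. Tumour cells were sorted as LAG3-tdT- (untraced), LAG3-tdT+ (traced, without surface LAG3) and LAG3+tdT+ (traced, with surface LAG3), and lymph node cells as CD44+tdT- and CD44+tdT+. The 6 gene expression libraries held 77509396, 63364847, 67071873, 145621006, 119302739 and 95013637 UMIs. After filtering, each tumour gate had 3 samples at day 11 and at day 19, except for 2 samples of day 11 LAG3+tdT+, and each lymph node gate had 3 samples at each day. Single samples remained for lymph nodes at day 72 and for lymph nodes called non-tumor in the hashtag sheet. Tumour samples were uneven in size. At day 19, LAG3-tdT+ had 385, 4155 and 34 cells with medians of 3570, 3013 and 3436 UMIs. LAG3+tdT+ had 121, 2499 and 141 cells with medians of 4852, 8724 and 14438 UMIs, and LAG3-tdT- had 813, 795 and 497 cells with medians of 4541, 3962 and 5013 UMIs. The day 11 tumour samples had between 30 and 391 cells and the lymph node samples of both days between 374 and 1954.

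The first question was how far traced LAG3+ cells in the tumour differ from cells without tracing or surface LAG3. At day 19, LAG3+tdT+ cells had far less RNA of Tcf7, the transcription factor of naive, memory and stem-like T cells, and more RNA of the exhaustion genes Pdcd1, Havcr2 and Tox than LAG3-tdT- cells. Tcf7 (ENSMUSG00000000782, chromosome 11, 52252371 to 52283014, GRCm38) was at 29.6 ± 37.9 CPM against 262 ± 77.8 CPM (SD, n = 3 each), a log2 fold change of -3.50 ± 0.70 (SE, adjusted p = 0.00084). Pdcd1, which encodes the receptor PD-1 (ENSMUSG00000026285, chromosome 1, 94038305 to 94052553), was at 468 ± 25.2 against 179 ± 28.8 CPM and rose by 1.38 ± 0.24 (adjusted p = 0.000249). Havcr2, which encodes TIM-3 (ENSMUSG00000020399, chromosome 11, 46454935 to 46481255), rose by 2.58 ± 0.63 (adjusted p = 0.00446), and Tox, a factor of exhausted T cells, by 1.40 ± 0.29 (adjusted p = 0.00105). Slamf6, a surface marker of progenitor exhausted cells (ENSMUSG00000015314, chromosome 1, 171917515 to 171953170), fell from 58.6 ± 21.2 to 15.3 ± 5.14 CPM (log2 -2.04 ± 0.34, adjusted p = 0.00018).

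**Figure D1:**
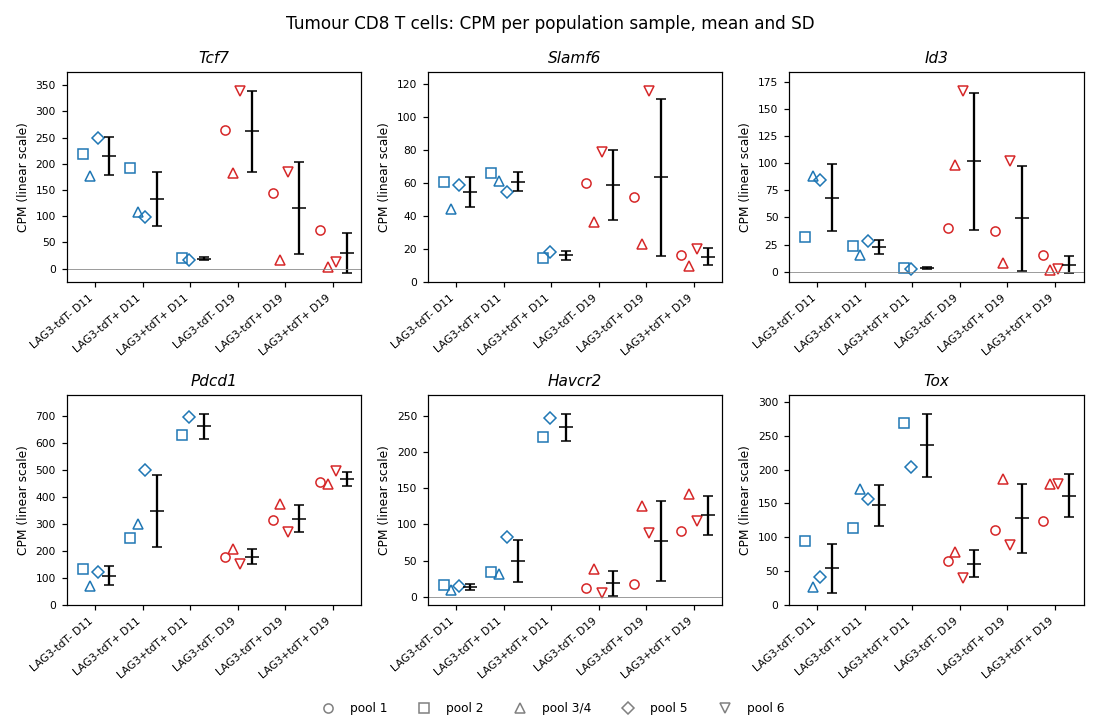
CPM of 6 genes (y axis, linear scale) in the tumour gates at day 11 (blue) and day 19 (red), with a marker for each pool and the mean ± SD in black. The mean of Tcf7 is highest in LAG3-tdT- and lowest in LAG3+tdT+ cells, with single day 19 samples overlapping, while the mean of Pdcd1 runs the other way, with 468 ± 25.2 CPM in the day 19 LAG3+tdT+ samples.

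In day 19 LAG3+tdT+ cells, Serpine2 rose by 5.67 ± 0.58 (adjusted p = 1.15e-06), Spp1, which encodes osteopontin, by 5.65 ± 0.73 to 93.2 ± 14.2 CPM, the opioid precursor Penk by 6.24 and the granzyme genes Gzmd, Gzmf and Gzme by 7.62, 5.32 and 6.00. The growth factor gene Csf2 rose by 4.03 and the chemokine gene Ccl9 by 4.73. Igfbp4 fell by 7.95 ± 0.94. Il7r, the receptor of a survival cytokine, fell by 3.04 ± 0.62, and Id3, a factor of memory T cells, by 4.86 ± 0.72. Gzmb had a log2 fold change of 1.17 ± 0.65 (adjusted p = 0.188), and of 1.35 with the pool as a block (adjusted p = 0.00136).

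By groups, 15 of 18 central memory and naive genes fell and 0 rose (adjusted over the list alone, also 15), among them S1pr1 and Klf2, which keep T cells circulating, by 4.47 and 3.62. The list passed at adjusted p = 1.4e-15, but with adjusted p = 0.0598 with an estimated correlation. Of 15 stemness factors, 13 fell (adjusted p = 0.0598 with an estimated correlation), and of 19 interferon response genes 15 fell, such as Oasl2 by 3.51 and Ifit3 by 2.21 (adjusted p = 0.279 with an estimated correlation). Terminal exhaustion genes, Lag3 of the sort among them, rose in 11 of 23 cases and fell in 1, adjusted over the list alone in 15 and 1. Tnfrsf9 was at 3.12 and Prf1, which encodes perforin, at 2.68 (adjusted p = 0.159 for the list with an estimated correlation). Of 20 cycling genes 17 rose, such as Ccnb1 by 2.41 and Cdk1 by 2.08, of 15 glycolysis genes 9, such as Slc16a3 by 1.80 and Hk2 by 1.53, and of 20 oxidative phosphorylation genes 6. Their adjusted p values were 0.312, 0.0598 and 0.34 with an estimated correlation. Markers of NK and gamma-delta T cells were lower in these LAG3+tdT+ samples, 3 of 4 passing, with Trdc at -5.20 and Tyrobp at -3.14 (adjusted p = 0.15 for the list with an estimated correlation). Of the other lists, the homing, stem-like, ribosomal, immediate early, cytokine, hypoxia, cholesterol, inhibitory receptor and exhaustion factor lists also passed with the preset correlation and none with an estimated one. The cytotoxic list had adjusted p = 0.0668, or 0.0444 with the pool as a block. The remaining 9 lists did not pass, with adjusted p between 0.0911 for B cells and 0.671 for costimulatory receptors.

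In all, 1242 genes were higher and 1616 lower in day 19 LAG3+tdT+ than in LAG3-tdT- cells, 43.46% of calls higher, or 54.37% with RLE scaling. In pools 1, 3/4 and 6 taken alone, 98.01%, 99.65% and 99.86% of these genes moved the same way. These genes were called with the same samples, so such shares are high by selection. Here and in the comparisons below they are no separate support. Of 96 named genes past the threshold, 63 kept their call whichever of the 6 samples was left out, Tcf7, Pdcd1, Slamf6, Havcr2 and Tox among them. The count was 1664 without the LAG3-tdT- sample of pool 6, 1603 and 1857 without the LAG3+tdT+ sample of pool 6 and of pool 3/4, and 57 without cells with 2 or more cycling UMIs, a limit that most cells of every sample met. After thinning to 1500 UMIs, a Tcf7 UMI was seen in 5.68 ± 7.52% of LAG3+tdT+ and 28.2 ± 5.82% of LAG3-tdT- cells (unthinned 13.9% and 54.0%), and a Pdcd1 UMI in 45.0% and 16% (unthinned 79.6% and 27.2%). In B cell-like barcodes with a median of 2612 UMIs these shares were 0.774% and 0.196%. Both had an exact permutation p = 0.1, the smallest that 3 against 3 samples can give, and an adjusted p = 0.2105 over 80 tests.

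At day 11, LAG3+tdT+ cells had Pdcd1 at 663 ± 47.2 CPM (n = 2) against 110 ± 34.5 CPM (n = 3), a rise of 2.48 ± 0.28 (adjusted p = 1.42e-05), Havcr2 at 234 ± 18.6 against 13.3 ± 4.06 CPM (3.95 ± 0.85, adjusted p = 0.00647) and Tcf7 at 19.1 ± 2.69 against 215 ± 36.6 CPM (-3.50 ± 0.84, adjusted p = 0.0128). Tox rose by 1.94 ± 0.35 (adjusted p = 0.00177) and Slamf6 fell by 1.87 ± 0.44 (adjusted p = 0.012). Spp1 rose by 6.99 ± 1.07 and Ccl3, a chemokine gene of activated T cells, by 5.83 ± 0.97 to 1350 ± 1140 CPM. Gzmf, Il1r2 and Gldc had 0 UMIs in LAG3-tdT- cells and were at least 40-fold, 27.8-fold and 15.6-fold higher in LAG3+tdT+ cells. Trdc, a marker of gamma-delta T cells, had 0 UMIs in LAG3+tdT+ cells. It was at least 7.57-fold higher in LAG3-tdT- cells, on 15 UMIs. Terminal exhaustion genes rose in 12 of 23 cases (18 adjusted over the list alone), inhibitory receptors in 7 of 14, cytokines and chemokines in 6 of 17 and cycling genes in 12 of 20, while 9 of 18 central memory genes and 6 of 15 stemness factors fell. Of 27 lists, 18 passed with the preset correlation and 0 with an estimated one, where the lowest adjusted p was 0.126.

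At day 11, 421 genes were higher and 341 lower, or 993 and 866 with the pool as a block, and 100% and 99.87% moved the same way in pools 2 and 5. The calls of Pdcd1 and Tox held without any 1 of the 5 samples. That of Havcr2 ended without the LAG3-tdT- sample of pool 5, and that of Tcf7 without that sample or either LAG3+tdT+ sample. That of Slamf6 ended without that LAG3-tdT- sample or the LAG3+tdT+ sample of pool 2. The count was 173 without that LAG3-tdT- sample, 389 and 232 without the LAG3+tdT+ sample of pool 2 and of pool 5, and 0 without cells with cycling UMIs. Days 11 and 19 shared 314 genes higher and 300 lower, where independent lists would share 46.9 and 49.4, and 0 genes went opposite ways. Here and below, such an expected number takes every gene as equally likely to be called. Genes differ in expression, however, and the comparisons share 1 fit. Part of the excess may therefore arise without a repeated difference. A test of the day by gate difference called 0 genes with edgeR, 483 at an unadjusted p under 0.05, 0 with DESeq2 and limma-voom and 2 with the pool as a block.

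The next question was how traced cells without surface LAG3 differ from traced cells with it. At day 19, LAG3-tdT+ cells had more RNA of Slamf6, Id3, Klf2 and Gzma and less of Csf2, Penk and Tnfsf4 than LAG3+tdT+ cells (n = 3 each). Slamf6 rose from 15.3 ± 5.14 to 63.6 ± 47.5 CPM (log2 1.64 ± 0.38, adjusted p = 0.0129), Id3 from 6.48 ± 7.68 to 49.3 ± 48.3 CPM (2.93 ± 0.80, adjusted p = 0.0264) and Klf2 from 48.7 ± 20.3 to 277 ± 213 CPM (2.37 ± 0.43, adjusted p = 0.00475). Gzma, a granzyme gene, rose by 3.66 ± 0.93 (adjusted p = 0.02). Csf2 fell by 5.56 ± 0.93 from 78.8 ± 67.9 to 0.652 ± 1.13 CPM (adjusted p = 0.00368) and Penk by 4.52 ± 0.92. Tnfsf4, which encodes the costimulatory ligand OX40L, fell by 3.76 ± 0.67. Tcf7 had a log2 fold change of 2.04 ± 0.73 (adjusted p = 0.0754), which passed with the pool as a block (adjusted p = 0.0202). Pdcd1, Havcr2, Tox and Gzmb had values of -0.52, -0.55, -0.23 and -0.48, none of which passed (adjusted p = 0.17, 0.621, 0.663 and 0.693).

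Of 19 interferon response genes 9 rose, 18 adjusted over the list alone, such as Ifit3 by 2.50 ± 0.64 and Rsad2 by 2.40. Of 15 stemness factors 9 rose, such as Lef1 by 1.90, and of 18 central memory and naive genes 7, such as S1pr1 by 3.54 and Klf3 by 3.21. These 3 lists had adjusted p = 1.5e-09, 1e-08 and 6.07e-07 with the preset correlation, and each had adjusted p = 0.319 with an estimated correlation. Glycolysis genes fell in 6 of 15 cases, such as Pgam1 by 1.13 and Tpi1 by 1.08 (adjusted p = 0.319 with an estimated correlation). Of 20 cycling genes 0 passed singly, with a median of -1.07 (adjusted p = 2.2e-06, or 0.486 with an estimated correlation). Among the cytokines, Xcl1 fell by 3.06 and Il2, a growth factor of T cells, rose by 5.32, and of the costimulatory receptors Tnfrsf9 and Tnfrsf4 fell by 2.42 and 2.16. The terminal exhaustion list did not pass (adjusted p = 0.321), with Prf1 falling by 2.01. The homing, T cell receptor, killer lectin, oxidative phosphorylation, immediate early and effector lists passed with the preset correlation alone, so that 11 of 27 lists passed in all and 0 with an estimated correlation. Myeloid and gamma-delta T cell markers moved too: Apoe rose by 3.22 and Trdc by 3.42, and Apoe went to -0.50 with HTODemux and to -1.002 without the CD8 and contaminant filter.

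In this comparison 485 genes were higher and 449 lower in LAG3-tdT+ cells, 51.93% of calls higher, or 40.92% with RLE scaling. Within pools 1, 3/4 and 6, 100%, 99.89% and 96.15% of these genes moved the same way, with medians of 1.11, 0.63 and 1.58 in the called direction, and 2365 genes passed with the pool as a block. The calls leaned on single samples. Only 5 genes passed without the LAG3-tdT+ sample of pool 1, 19 without the LAG3+tdT+ sample of pool 6, 579 without the 34 cells of the LAG3-tdT+ sample of pool 6 and 1650 without the LAG3-tdT+ sample of pool 3/4. Of 65 named genes, 1 (Tctex1d2) kept its call throughout. After thinning, a Slamf6 UMI was seen in 8.74 ± 6.25% of LAG3-tdT+ and 2.72 ± 1.00% of LAG3+tdT+ cells (exact permutation p = 0.1, adjusted p = 0.2105, unthinned 20% and 14.6%), with 3.46% and 3.38% in the nearest samples. A Tcf7 UMI was seen in 15.9 ± 11.3% and 5.68 ± 7.52% (exact permutation p = 0.2, unthinned 30% and 13.9%). The share with a Pdcd1 UMI was 33.2 ± 7.22% and 45.0 ± 6.39% (exact permutation p = 0.2, unthinned 50.7% and 79.6%), and in B cell-like barcodes with a median of 2612 UMIs the shares were 14.3%, 0.774% and 0.196% for Slamf6, Tcf7 and Pdcd1. With only the 6 samples of these gates in the fit 0 genes passed, without cells with cycling UMIs 1, and without library 3, which held all LAG3-tdT+ cells of pool 3/4, 1701.

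At day 11, Spp1 was at 9.17 ± 8.01 CPM in LAG3-tdT+ (n = 3) and 176 ± 87.7 CPM in LAG3+tdT+ cells (n = 2) and fell by 3.83 ± 0.69, and Ccng1, a p53 target, fell by 1.10 ± 0.19 (both adjusted p = 0.0377). These were the 2 genes past the threshold, against 1147 at an unadjusted p under 0.05, 53 with DESeq2, 1 with limma-voom and 134 with the pool as a block. Both calls ended without the LAG3-tdT+ sample of pool 2 or of pool 3/4 or either LAG3+tdT+ sample, while 23 genes passed without the LAG3-tdT+ sample of pool 5. Slamf6 had a value of 1.93 (adjusted p = 0.0777) and Tcf7 of 2.75 (0.21), which both passed with the pool as a block (0.0141 and 0.0474). Havcr2 had a value of -2.09 (adjusted p = 0.252) and Pdcd1 of -0.90 (0.194). The terminal exhaustion list was lower, 9 members adjusted over the list alone, and the central memory list higher, with 7. They had adjusted p = 4.37e-05 and 2.28e-08, and 12 lists passed in all, 0 of them with an estimated correlation, where the lowest adjusted p was 0.258.

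Traced and untraced cells without surface LAG3 were compared next. At day 19, LAG3-tdT+ cells had less RNA of Igfbp4, Satb1, Bcl2 and several killer lectin genes (n = 3 each). Igfbp4 fell by 4.53, the chromatin organizer Satb1 by 2.26 ± 0.36 (adjusted p = 0.00141) and Bcl2, which protects from cell death, by 1.93 ± 0.41. The NK cell receptor genes Klra7 (ENSMUSG00000067599, chromosome 6, 130218605 to 130233322), Klra6, Klrb1c and Klra1 fell by 6.57 ± 0.79, 5.38, 5.18 and 4.34, with Klra7 at 0.15 ± 0.261 against 40.6 ± 21.1 CPM. Gpd2, an enzyme of glycerol metabolism, rose by 1.36 ± 0.29 and Fam129a by 0.96 ± 0.22. Tox had a value of 1.17 (adjusted p = 0.0546) and Pdcd1 of 0.86 (0.102), which both passed with the pool as a block (0.0139 and 0.0184). Values that did not pass either way were those of Havcr2 at 2.03 (0.178), Tcf7 at -1.46 (0.435) and Slamf6 at -0.40, whose mean ran the other way (63.6 ± 47.5 against 58.6 ± 21.2 CPM). The killer lectin list fell with 4 of 14 members past the threshold (5 adjusted over the list alone, adjusted p = 0.0497 with an estimated correlation), and central memory and naive genes with 5 of 18 (9, and 0.118). The terminal exhaustion list was higher with a median of 0.86 and 0 members past the threshold (6 adjusted over the list alone, adjusted p = 0.0929 with an estimated correlation). Markers of NK and gamma-delta T cells were lower with a median of -1.63 (adjusted p = 0.021, or 0.0929 with an estimated correlation). Of 27 lists 17 passed, 18 with the pool as a block, where the effector list was added, and 1 with an estimated correlation.

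In all, 6 genes were higher and 87 lower, or 68 and 257 with the pool as a block, 54 in total with DESeq2 and 356 with limma-voom. Within pools 1, 3/4 and 6, 100%, 100% and 94.62% moved the same way. None of the 16 named calls held without the 4155 cells of the LAG3-tdT+ sample of pool 3/4, where 0 genes passed. The count was 215 without the LAG3-tdT+ sample of pool 1, 160 and 35 without the LAG3-tdT- sample of pool 3/4 and of pool 6, 8 with only these groups in the fit, 11 without cells with cycling UMIs and 61 with HTODemux. At day 11, Pdcd1 rose by 1.58 ± 0.26 from 110 ± 34.5 to 351 ± 134 CPM and Eea1, of early endosomes, by 1.93 ± 0.33 (both adjusted p = 0.0229, n = 3 each), and Ubash3b, a phosphatase gene, by 1.27 ± 0.24 (adjusted p = 0.0398). Poll, a DNA polymerase gene chosen after its values were seen, was the last of 4 genes past the threshold (adjusted p = 0.0391), against 830 at an unadjusted p under 0.05, 12 with DESeq2, 1 with limma-voom and 12 with the pool as a block. The named calls ended without any of 5 of the 6 samples. The terminal exhaustion list was higher, 9 members adjusted over the list alone (adjusted p = 3.1e-06), 1 of 11 lists that passed, 0 with an estimated correlation, where the lowest adjusted p was 0.358.

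In the lymph nodes, traced cells stood apart from untraced CD44+ cells by exhaustion-related genes, while no change of Tcf7 was detected. At day 19, Pdcd1 rose from 7.21 ± 2.53 to 68.4 ± 16.8 CPM (log2 3.25 ± 0.28, adjusted p = 5.8e-08, n = 3 each), Havcr2 from 0.158 ± 0.145 to 12.6 ± 7.86 CPM (5.97 ± 1.37, adjusted p = 0.00563), Tox from 52.2 ± 5.24 to 121 ± 28.9 CPM (1.2 ± 0.29, adjusted p = 0.00732) and Slamf6 from 74.1 ± 7.77 to 196 ± 49.5 CPM (1.40 ± 0.30, adjusted p = 0.00335). Tcf7 was at 364 ± 60.4 and 436 ± 24.3 CPM (-0.26 ± 0.58, adjusted p = 0.921). Among the largest increases were Cd40lg, the ligand by which helper T cells stimulate B cells (ENSMUSG00000031132, X chromosome, 57212143 to 57224042), by 4.14 ± 0.43 to 56.4 ± 16 CPM (adjusted p = 4.02e-07). Il2 rose by 4.16 ± 0.88, Lgals3, which encodes galectin-3, by 4.15 ± 0.42, Gzmk by 4.20, Penk by 4.81 and Spp1 by 4.74. Ly6c2, a marker of memory CD8+ T cells, fell by 2.11 ± 0.50 to 353 ± 213 CPM, Pde2a by 2.65, Plac8 by 2.24 and Gzmm by 2.11.

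**Figure D2:**
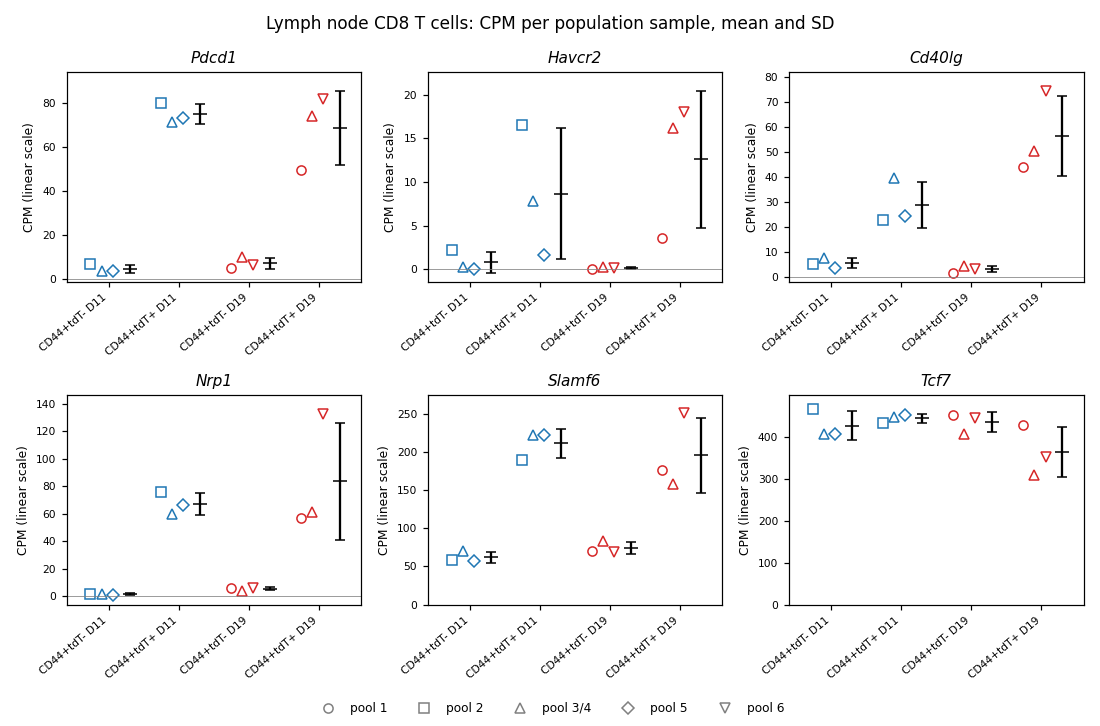
CPM of 6 genes (y axis, linear scale) in the lymph node gates at day 11 and day 19, with a marker for each pool and the mean ± SD in black. Pdcd1, Cd40lg and Slamf6 are higher in every CD44+tdT+ sample than in any CD44+tdT- sample of the same day, while Tcf7 is at 364 ± 60.4 and 436 ± 24.3 CPM at day 19.

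Terminal exhaustion genes rose in 15 of 23 cases and fell in 0 (19 and 0 adjusted over the list alone), with Tigit at 3.18 and Ccl3 at 3.68. Exhaustion factors rose in 13 of 18, with Tox2 at 3.99, Maf at 3.11 and Irf4 at 1.95. Cytokines and chemokines in 10 of 17, with Il21 at 4.82, and inhibitory receptors in 6 of 14. Costimulatory receptors rose in 4 of 10, with Tnfrsf4 at 3.78 and Icos at 2.33, and tissue residency genes in 4 of 12, with Rgs1 at 2.17 and Itgae at 1.53. All 7 genes of the CD4 and regulatory T cell list rose, with Foxp3 at 2.70 and Cd4 itself at 2.46 (adjusted p = 0.0442). The antibody gene Igkc rose by 5.34 ± 1.69 (adjusted p = 0.0459) and turned to -0.705 without the CD8 and contaminant filter, and Cd74, expressed by antigen-presenting cells, had a value of 2.69 ± 1.02 (adjusted p = 0.106). These 7 lists held with an estimated correlation, with adjusted p = 0.00567, 0.00171, 0.00176, 0.0139, 0.00176, 0.0236 and 0.00176 in this order. They are not independent, since lists share members in this and all comparisons. Pdcd1 and Tigit, for instance, are in the terminal exhaustion and inhibitory receptor lists, and Cd40lg is in the costimulatory and CD4 lists. Cycling genes rose in 12 of 20 cases, such as Ccnb1 by 2.70, ribosomal protein genes fell in 6 of 20, and central memory genes fell in 4 of 18, such as Lef1 by 1.43 and Satb1 by 1.74. With an estimated correlation these had adjusted p = 0.25, 0.131 and 0.139. The effector, mitochondrial and stemness factor lists passed with the preset correlation alone, and the cytotoxic list only with the pool as a block (adjusted p = 0.0112 against 0.0828). The interferon list had a median of 0.05 and did not pass (adjusted p = 0.986).

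At day 19, 738 genes were higher and 272 lower in CD44+tdT+ cells, or 1170 and 726 with the pool as a block and 953 and 618 with only these groups in the fit. Within pools 1, 3/4 and 6, 99.9%, 100% and 99.11% moved the same way. Of 73 named calls, 43 held without any 1 sample, Pdcd1, Slamf6, Havcr2, Cd40lg and Il2 among them. The call of Tox ended without the pool 6 sample of either gate. The count was 577 and 487 without the CD44+tdT- sample of pool 1 and of pool 6, 664 and 618 without the CD44+tdT+ sample of pool 3/4 and of pool 6, and 168 without cells with cycling UMIs. After thinning, a Slamf6 UMI was seen in 25.3% of traced and 8.74% of untraced cells and a Pdcd1 UMI in 8.58 ± 1.87% and 0.613 ± 0.182% (exact permutation p = 0.1 and adjusted p = 0.2105 for both, unthinned 47.0% and 22.2%, 17.6% and 1.85%), and a Tcf7 UMI in 42.7% and 42.4% (unthinned 67.2% and 76.6%). B cells express Slamf6, and their share with a Pdcd1 UMI was 0.196%.

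At day 11 many of the same genes differed between the lymph node gates. Pdcd1 rose by 3.91 ± 0.30 (adjusted p = 4.09e-09), Slamf6 by 1.77 ± 0.30 to 211 ± 18.9 CPM, Tox by 1.19 ± 0.28 and Cd40lg by 2.36, and Nrp1, which encodes the receptor neuropilin-1, by 5.59 ± 0.48 from 1.29 ± 0.774 to 67.4 ± 8.09 CPM (adjusted p = 2.3e-08, n = 3 each). The growth factor genes Il2 and Csf1 rose by 4.65 and 4.44, the surface protein genes Cd200 and Ctla4 by 4.49 and 3.35, and Tox2 and Ikzf2 by 4.28 and 2.22. Tcf7 had a value of 0.06 ± 0.58 (adjusted p = 0.986) and Havcr2 of 3.16 (adjusted p = 0.0611, or 0.0201 with the pool as a block). G0s2 fell by 3.02, Gzmm by 2.65, Igfbp4 by 2.41 and the homing receptor gene Ccr9 by 2.14. Cycling genes rose in 18 of 20 cases, such as Ube2c by 3.95 (adjusted p = 0.155 with an estimated correlation). The same 7 lists as at day 19 held with an estimated correlation, with adjusted p from 0.00193 for exhaustion factors to 0.0401 for tissue residency. Cd74 rose by 3.58 ± 1.06 from 22.6 ± 16.6 to 275 ± 252 CPM (adjusted p = 0.0275) and turned to -0.732 without the CD8 and contaminant filter.

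In all, 820 genes were higher and 332 lower at day 11, or 1289 and 869 with the pool as a block, and 100% moved the same way in each of the 3 pools. The count was 720 and 668 without the CD44+tdT- sample of pool 3/4 and of pool 5, 753 without the CD44+tdT+ sample of pool 3/4, and 110 without cells with cycling UMIs, and 53 of 80 named calls held without any 1 sample. Days 11 and 19 shared 585 genes higher and 186 lower, where independent lists would share 54.3 and 8.1, and the test of the day by gate difference called 0 genes with edgeR, 82 at an unadjusted p under 0.05, and 0 with DESeq2, limma-voom and the block. Lymph node and day 19 tumour contrasts overlapped in part. Of the genes higher in traced nodes, 306 were also higher in tumour LAG3+tdT+ than in LAG3-tdT- cells (82.2 for independent lists) and 36 were lower.

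Traced cells were then compared between sites. The gates differ too: node cells were sorted on CD44, tumour cells on the absence of surface LAG3, so site and gate are mixed. In pool 3/4 the sites also lie in different libraries. At day 19, lymph node CD44+tdT+ cells had more RNA of Itgae, which encodes the integrin CD103, than tumour LAG3-tdT+ cells (144 ± 17.4 against 8.17 ± 7.39 CPM, log2 4.87 ± 0.58, adjusted p = 1.4e-06, n = 3 each). Wnt10a was higher by 6.49 ± 0.81, the chemokine receptor genes Ccr6 and Ccr10 by 5.56 and 5.76, Cd40lg by 5.20 ± 0.57 and Slamf6 by 2.14 ± 0.35. Tcf7 was 1.94 ± 0.67 higher (adjusted p = 0.0496), a call that ended without any of the 3 lymph node samples or without the tumour sample of pool 3/4. Gzmb fell by 4.41 ± 0.75 from 846 ± 550 to 39.3 ± 42.6 CPM (adjusted p = 0.000165), Dusp5, a phosphatase of the MAP kinase pathway, by 4.52 ± 0.29 (adjusted p = 9.11e-11), Pdcd1 by 2.27 ± 0.25 and Havcr2 by 2.79, and the metallothionein genes Mt1 and Mt2 by 4.34 and 6.17. Tox had a value of -0.20 (adjusted p = 0.737). Of 18 cytotoxic genes 12 fell, of 23 terminal exhaustion genes 14, of 12 hypoxia genes 9, such as Vegfa by 3.61. Of 15 glycolysis genes 10 fell, such as Slc16a3 by 3.90, of 17 effector genes 10, of 20 immediate early genes 9, such as Atf3 by 3.65, and of 18 exhaustion factors 8, such as Nr4a1 by 3.36. These 7 lists held with an estimated correlation, with adjusted p from 0.000475 for hypoxia to 0.0413 for terminal exhaustion.

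At day 19, 801 genes were higher and 819 lower in the lymph nodes, 2510 in total with the pool as a block and 2545 with limma-voom, with 98.15%, 99.94% and 83.33% moving the same way in pools 1, 3/4 and 6. The count fell to 574 without the tumour sample of pool 3/4, 590 without library 3, 1030 without the node sample of pool 1, 867 with only these groups and 385 without cells with cycling UMIs. Gzme, Gzmd and Gzmf turned direction without library 3, to 1.59, 2.84 and 0.99. At day 11, Itgae rose by 3.89 ± 0.53 and Wnt10a by 5.43 ± 0.72 in the nodes, while Gzmb fell by 4.72 ± 0.76 (adjusted p = 8.3e-05), Pdcd1 by 2.24 and the killer lectin genes Klrc1 and Klre1 by 4.64 and 4.60. Ccl9 had 0 UMIs in the nodes and was at least 9.69-fold lower. There 852 genes were higher and 986 lower, 2763 in total with the pool as a block, 960 without the tumour sample of pool 5, 1149 with only these groups and 188 without cells with cycling UMIs, and 97.93%, 98.69% and 99.89% moved the same way in pools 2, 3/4 and 5. Of 27 lists 12 passed, 6 of them with an estimated correlation (killer lectins at adjusted p = 0.0388). Both days shared 444 genes higher and 605 lower (61.2 and 72.4 for independent lists).

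The last replicated question was what changed from day 11 to day 19 within a gate. Time since tamoxifen also differs between these days, and its effect cannot be separated from that of the day. In LAG3+tdT+ cells (n = 3 at day 19 and 2 at day 11), Csf2 rose by 4.65 ± 1.02 from 4.58 ± 5.66 to 78.8 ± 67.9 CPM (adjusted p = 0.0317) and Tnfsf4 by 4.04 ± 0.79. Izumo1r, the folate receptor gene of helper and regulatory T cells, fell by 1.90 ± 0.30 (adjusted p = 0.00661), Egr3, an early gene of receptor signals, by 2.61, Nfatc1 by 1.15 and Tbx21, the effector factor T-bet, by 1.38. With the pool as a block the calls of Csf2, Tnfsf4, Egr3, Nfatc1 and Tbx21 ended (adjusted p = 0.658, 0.267, 0.0974, 0.063 and 0.108) and that of Izumo1r held. No pool held both days of this gate, so day and pool are fully confounded here. The block then rests on pool differences estimated from the other gates. Pdcd1 had a value of -0.50 (adjusted p = 0.309), Havcr2 of -1.03 (0.394) and Tcf7 of 0.24. Here 16 genes were higher and 37 lower, but 1 without the day 11 sample of pool 2, 6 without the day 19 sample of pool 6, 135 without that of pool 3/4, 0 with only these groups, 14 with the pool as a block, 99 with DESeq2 and 173 with limma-voom, and none of the 21 named calls held whichever sample was left out. Of 27 lists 11 passed, 8 with the pool as a block and 0 with an estimated correlation, where the lowest adjusted p was 0.329. The immediate early list was lower and the oxidative phosphorylation list higher (medians -0.595 and 0.262, both adjusted p = 0.000544), the former not with the block (0.0878).

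In the other gates 0 genes passed with edgeR between the days: 1162 at an unadjusted p under 0.05 for tumour LAG3-tdT- (4 with DESeq2, 0 with limma-voom, 5 with the pool as a block), 829 for tumour LAG3-tdT+ (1, 9 and 10), 117 for lymph node CD44+tdT- (1, 0 and 0) and 169 for lymph node CD44+tdT+ (2, 0 and 4). For example, Pdcd1 had values of 0.60 ± 0.26 in LAG3-tdT- and -0.12 in LAG3-tdT+ tumour cells and -0.14 in traced node cells, where Slamf6 was at -0.12 and Tcf7 at -0.29. Lists that passed with the preset correlation numbered 3, 3, 4 and 7 in these gates, 4, 10, 10 and 12 with the pool as a block, and 0 with an estimated correlation. Cycling genes were higher in LAG3-tdT- cells, with a median of 0.986 (adjusted p = 0.00626, or 0.963 with an estimated correlation). With the pool as a block, Gzmb passed in LAG3-tdT- and LAG3-tdT+ tumour cells and in traced node cells (log2 2.81, 2.36 and 2.68, adjusted p = 0.0126, 0.012 and 0.00642). Days were spread over pools, with 1 pool holding both days of these gates, so day and pool are largely confounded. The fits with a block link the days through that pool (3/4) alone and share its offsets. The values of Gzmb with the block are therefore not independent of each other. For LAG3-tdT-, that pool sets library 3 at day 11 against library 4 at day 19. The difference of the gate effect between days was tested as well for LAG3-tdT+ against LAG3+tdT+ and against LAG3-tdT- cells, with 0 genes past the threshold for each, 575 and 331 at an unadjusted p under 0.05, 1 and 0 with DESeq2 and 0 with limma-voom. For the 4 differences between days, 3, 2, 2 and 8 lists passed with the preset correlation (LAG3-tdT+ against LAG3+tdT+, LAG3+tdT+ against LAG3-tdT-, LAG3-tdT+ against LAG3-tdT- and the lymph node gates), 4, 8, 2 and 11 with the pool as a block and 0 with an estimated correlation.

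Single lymph node samples extend this to day 72 and to nodes called non-tumor, without a replicate check. At day 72, Pdcd1 was at 7.17 CPM (95% interval 5.21 to 9.63) in traced and 3.65 CPM (2.00 to 6.12) in untraced cells and Tcf7 at 488 and 459 CPM. Nrp1, chosen after its values were seen, was at 6.36 CPM (4.52 to 8.69) against 1.56 CPM (0.574 to 3.40). Itgae was at 89.8 CPM (82.4 to 97.6) against 49.0 CPM (42.2 to 56.5), while the chemokine gene Ccl5 was at 238 against 733 CPM and Cxcr3 at 25.9 against 62.6 CPM. Of the 1010 genes that differed at day 19, 577 (57.13%) lay on the same side at day 72, with a median log2 value of 0.059. In library 1 the sheet gives node 1 for the day 19 node samples and node 2 for the day 72 ones. Day and node therefore cannot be told apart between them. Against the day 19 traced sample of the same library, the day 72 traced sample had log2 ratios of -2.90 for Pdcd1, -2.98 for Cd40lg and -3.27 for Nrp1 (the last 2 chosen after their values were seen), of 1.09 for Lef1, 2.01 for Igfbp4 and 0.06 for Tcf7. In the CD4 and regulatory T cell list 0 of 3 genes were higher (median -2.98, percentile 0.01 of random lists). In the myeloid list it was also 0 of 3 (median -2.16, percentile 0.07). Of 18 central memory and naive genes 16 were higher (median 0.52, percentile 100), and of 20 cycling genes 1 was (median -3.70, percentile 0). In the untraced samples of the same library and days, these 2 lists moved the same way by less, with 13 of 18 central memory genes higher (median 0.11, percentile 100) and 2 of 13 cycling genes (median -0.34, percentile 0). Pdcd1 and Nrp1 were also lower by less, at -0.34 (14 against 22 UMIs) and -1.73 (6 against 26 UMIs). Cd40lg went the other way, at 1.34 (17 against 8 UMIs). The terminal exhaustion list was at a median of 0.10 (9 of 14 higher, percentile 93.19), against -2.20 (1 of 18) in traced cells.

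Whether non-tumor nodes come from mice without a tumour or only do not drain one is not given in the sources used here. In them the traced sample had Nrp1 at 50.2 CPM (44.2 to 56.9) against 3.36 CPM (1.68 to 6.02) in the untraced one, Tnfrsf4 at 54.1 against 7.04 CPM, S100a4 at 295 against 29.7 CPM and Pdcd1 at 24.5 CPM (20.4 to 29.3) against 10.7 CPM (7.46 to 14.9), with Tcf7 at 515 and 511 CPM. Ly6c2 was at 357 against 1000 CPM. Of the 1010 genes that differed at day 19, 928 (91.88%) lay on the same side. All 17 cycling genes above the limit were higher (median 1.30, percentile 100), and 17 of 19 terminal exhaustion genes (median 0.77, percentile 100). Markers of CD4 and regulatory T cells were higher too, 6 of 6 (median 2.88, percentile 100), with Foxp3 at 23.3 against 2.75 CPM, chosen after its values were seen.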

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

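Tests chosen only after the result was seen were those of library 3 and of the added settings, of free RNA in the lymph nodes and of NK cells alone. Library 3, which holds the day 11 tumour samples of pool 3/4 and the day 19 LAG3-tdT+ sample, lay far from the other 5 libraries in 4 of 8 measures. It had a median of 1852 UMIs per barcode (next library 4494), 0.3693% of hashtag UMIs on tags of the human set (next 0.1327%), 45.85% of filtered barcodes assigned to 1 tag (next 76.75%) and 9.82% of barcodes with 2 or more melanoma UMIs (next 0.56%). The gaps to the next library took 0.665, 0.799, 0.655 and 0.944 of the whole range, above Dixon's limit for 6 values, which chance alone passes in about 1 in 20 measures.

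The weighed pattern of the day 19 tumour was the difference between LAG3-tdT+ and LAG3+tdT+ cells, since library 3 holds most LAG3-tdT+ cells. Without library 3, the called genes had a median change of 1.357 in their direction against 1.091 with it, a ratio of 1.24. The difference was thus not confined to that library. However, the genes were called with the same samples. Pool 3/4 had the lowest median change within a pool (0.63, against 1.11 and 1.58). Leaving out its LAG3-tdT+ sample was therefore likely to raise the median whatever the cause. Whether free hashtags and shallow barcodes of library 3 add to the difference cannot be decided this way. RNA of myeloid cells in the LAG3+tdT+ gate was weighed as well. Without the lineage filter the median change of Lyz2, Apoe, C1qa, C1qb, Ctss and Cd74 (LAG3+tdT+ over LAG3-tdT+) was -0.35 of that of Spp1, which was 2.88. Lyz2, C1qa, C1qb, Ctss and Cd74 were at -1.38, -1.40, -1.49, -0.51 and -0.64, but Apoe was at 1.00, the direction of Spp1. A net excess of myeloid RNA in the LAG3+tdT+ gate was thus not seen in most of these genes. Myeloid RNA in the LAG3-tdT+ gate would also lower the median, so some in the LAG3+tdT+ gate is not excluded. At equal depth, the shares of cells with a Slamf6 UMI just did not overlap between the gates, while those of Tcf7 and Pdcd1 did (exact permutation p = 0.1, 0.2 and 0.2). The difference in depth for the other genes and the dependence on single samples stay open.

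In lymph nodes, the rise of Cd40lg, Izumo1r, Nrp1 and Ctla4 in traced CD44+ cells was weighed because CD4 T cells express all 4 genes. With cells that held a UMI of Cd4, Foxp3 or Zbtb7b left out, the median change was 3.549 against 3.522, a ratio of 1.01, with Cd40lg at 4.25 and Nrp1 at 3.93. Free RNA of a library would enter the droplets of both gates, but the lowest median ratio within a pool was 3.43 on the log2 scale. Both gates shared a library in every pool, so this ratio restates the gate difference and is no separate test. CD4 T cells seen by these UMIs were therefore argued against. Free RNA spread evenly over the droplets of both gates would not give such a ratio, while doublets of a CD4 and a CD8 T cell stay open. Among day 19 traced cells with a Cd40lg UMI, 4.9% to 6.64% had a Cd4 UMI, against 2.2% to 2.91% of all.

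The fall of Klra6 and Klra7 from LAG3-tdT- to LAG3-tdT+ tumour cells at day 19 was weighed against NK or gamma-delta T cells in the LAG3-tdT- gate. The median change of Ncr1, Klrb1c, Tyrobp, Trdc and Klra8 was 0.62 of that of the 2 genes, which fits this explanation, although Ncr1 was at 0.316 CPM and Klra8 at 0.867 CPM. NK cells alone were argued against, since the Tyrobp lost with Klra7 was at most 0.07 of the ratio in NK-like barcodes, of which pools 1, 3/4 and 6 held 1, 26 and 3. Of 2105 LAG3-tdT- cells 128 had a Klra7 UMI, all 128 of them a Cd3 UMI, 60 a Cd8b1 UMI and 2 a Trdc UMI. Innate-like T cells within the gate stay open, and no biological explanation was tested.

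Lymph nodes that the hashtag sheet gives without a day entered no comparison, yet their traced samples had more Pdcd1 than the untraced sample of the same node. The log2 ratios were 4.46, 2.09, 0.98 and 3.61 in nodes 3, 4, 5 and 6.

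Other splits of the samples were counted for comparisons of 3 against 3, where 10 splits are too few for a share under 0.05. The real split gave the most genes, 1 of 10 splits, for LAG3-tdT+ against LAG3+tdT+ at day 19 (934, highest other 316), LAG3+tdT+ against LAG3-tdT- at day 19 (2858 and 1), LAG3-tdT+ against LAG3-tdT- at day 19 (93 and 25) and day 11 (4 and 2), the lymph node gates at day 19 (1010 and 0) and day 11 (1152 and 0), and lymph node against tumour traced cells at day 19 (1620 and 53) and day 11 (1838 and 0). For the days within LAG3-tdT-, LAG3-tdT+ and both lymph node gates the real value was 0, so that 10 of 10 splits give as many whatever the data, with at most 2 genes. For the differences between days of LAG3-tdT+ against LAG3-tdT- and of the lymph node gates the real value was also 0, so that the count of 100 of 100 drawn splits was fixed beforehand and tests nothing. Their highest other values, 348 and 847, point to a structure of the samples, of which the gate differences themselves are part, and are no evidence of any beyond these.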

How the results depend on the processing

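Settings added after seeing the data were Ighm left out of the contaminant limit, the ratio of 10 in library 3, library 3 left out, the highest Scrublet scores left out and cells with CD4 lineage UMIs left out. RLE scaling, at most 5% mitochondrial UMIs and the highest Scrublet scores left out moved no count of genes by over 1.5 times. The counts with and without the block had both been seen when the pairing of pools was checked. Where a left-out sample leaves a lone one, it is assumed to vary like the other groups. The cause was not tested for any value below, except that leaving out cells or samples lowers depth or replication. Cycling UMIs were in about 80% of cells, so that setting mostly removes cells. Comparison of cluster sizes was not run.

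Below, A is LAG3-tdT+ against LAG3+tdT+, B LAG3+tdT+ against LAG3-tdT-, C LAG3-tdT+ against LAG3-tdT-, P the lymph node gates and X lymph node against tumour traced cells, each with its day, and numbers are genes past the threshold. In the reported fit these were A19 934, A11 2, B19 2858, B11 762, C19 93, C11 4, P19 1010, P11 1152, X19 1620, X11 1838, and 53 between days in LAG3+tdT+ and 0 in the other gates and in all differences between days.

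With the pool as a replicate block (paired), A19 had 2365, A11 134, B11 1859, C19 325, C11 12, P19 1896, P11 2158, X19 2510 and X11 2763. Between days LAG3-tdT- had 5, LAG3-tdT+ 10, LAG3+tdT+ 14 and traced nodes 4, and the day difference of B 2. The ribosomal list between days in untraced nodes turned from higher to lower (adjusted p = 0.000188). Of 687 values of named genes, 653 kept their call with the block, 19 passed newly and 15 no longer passed. Of 513 list tests, 459 kept theirs, 41 passed newly and 12 no longer did. Tcf7 of X11 passed newly (adjusted p = 0.0103), as did Gzmb of B11 (0.000707) and Il7r of A19 (0.0171). Apart from these and those given with the results, the block changed no other call given in the results.

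Without a low-count filter A11 had 40, C11 11 and the day difference of A 4. With DESeq2 A11 had 53, C19 54, C11 12, and between days LAG3-tdT- 4, LAG3-tdT+ 1, LAG3+tdT+ 99, untraced nodes 1, traced nodes 2 and the day difference of A 1. With limma-voom A11 had 1, B11 354, C19 356, C11 1, X19 2545, and between days LAG3-tdT+ 9 and LAG3+tdT+ 173. A tag ratio of 10 left C11 at 1. With HTODemux A11 had 0, B11 171, C19 61, C11 0, LAG3+tdT+ between days 11 and the day difference of B 1, and Apoe turned to -0.497 in A19 and 0.135 in X19. Without the CD8 and contaminant filter A11 had 1 and C11 0, and Apoe turned to -1.002 in A19, Igkc to -0.705 in P19 and Cd74 to -0.732 in P11.

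Without cells with 2 or more cycling UMIs A19 had 1, A11 0, B19 57, B11 0, C19 11, C11 0, P19 168, P11 110, X19 385, X11 188, LAG3+tdT+ between days 1 and the day difference of B 1. Turned were Ctss to -0.078 in A19 and 0.055 in B19, Tpi1 to -0.181, Pgk1 to -0.001, Pkm to -0.1, Uqcrb to -0.14 and Atp5j to -1.762 in B11, Erf to 0.174 between days and Sqle to 3.444 in X11. With Ighm left out of the limit A11 had 17, C11 0, LAG3-tdT- between days 1, LAG3+tdT+ 102 and the day difference of B 2. With the ratio of 10 in library 3 A11 had 7 and C11 2. Without library 3 A19 had 1701, A11 9, C19 0, C11 0, X19 590, LAG3+tdT+ between days 84 and the day difference of A 3, and Egr3 turned to -0.369 in A19, and Gzme to 1.591, Gzmd to 2.836 and Gzmf to 0.988 in X19. Without cells with CD4 lineage UMIs A11 had 0, and with at least 50 cells A11 0 and C11 0. With only the groups compared A19 had 0, A11 8, C19 8, C11 1, P19 1571, X19 867, X11 1149 and LAG3+tdT+ between days 0.

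Leaving out 1 sample gave 5 to 1650 for A19, 0 to 23 for A11, 1603 to 3196 for B19, 173 to 512 for B11, 0 to 215 for C19, 0 to 11 for C11, 487 to 811 for P19, 668 to 1160 for P11, 574 to 1661 for X19 and 960 to 1825 for X11. Between days it gave 0 to 0 for LAG3-tdT- and both node gates, 0 to 1 for LAG3-tdT+ and 1 to 135 for LAG3+tdT+, and for day differences 0 to 20 for A, 0 to 1 for B and 0 to 0 for C and P. Gzmc ranged from -4.656 to 5.0 in X11, turning without the day 11 LAG3-tdT+ sample of pool 5. Without the day 19 LAG3-tdT+ sample of pool 3/4, Egr3 turned to -0.464 in A19 (highest 2.11), and Gzme to 1.574, Gzmd to 2.815 and Gzmf to 1.061 in X19 (lowest -8.618, -8.369 and -5.176). With an estimated correlation, 150 of 513 list tests no longer passed and 0 passed newly.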

Other observations

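This part reports values without a test, most of them from samples outside the comparisons, looked up after those had been seen. In the lymph nodes without a day (nodes 3, 4, 5 and 6), traced over untraced CD44+ cells had log2 ratios of 3.47, 2.69, 1.28 and 2.62 for Nrp1, 1.82, 1.25, 0.53 and 1.70 for Tox, and 6.23, 2.49, 0.07 and 3.71 for Gzmb. Cd40lg had 2.28, 0.96, 0.44 and 2.06, and Tcf7 had -0.25, -0.10, -0.01 and 0.06. Markers of CD4 T cells moved along, Cd4 by 2.36, 2.61, 0.16 and 3.19 and Foxp3 by 3.04, 4.69, 1.03 and 2.94. Of the 1010 genes that differed at day 19, 95.84%, 92.28%, 60.4% and 92.48% lay on the same side.

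At day 72 in untraced cells, against the day 19 sample of the same library but another node, the early genes Fos and Jun had log2 ratios of 0.85 and 0.64 (their list a median of 0.02, percentile 78.36), and the interferon response genes Ifit3 and Isg15 of -0.93 and -0.88. A Cd40lg UMI was seen in 11.57%, 10.96% and 20.86% of day 19 traced cells and in 0.75%, 1.08% and 1.19% of untraced cells, in pools 1, 3/4 and 6. These shares were not thinned to equal depth, and free RNA of Cd40lg was not gauged in B cell-like barcodes.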
